A study of Rattus norvegicus with 4 samples.

How the data were processed

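Liver RNA from rats was sequenced in 4 libraries, 2 from animals under forced activity alone and 2 from animals under forced activity with sleep restriction. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was purified and fragmented, and libraries were made with an Illumina kit and amplified by PCR. CASAVA, STAR 2.4.1d and the rat genome build rn6 are named in the submitters' processing notes, which give them no role or order. The counting program is not given in the sources used here.

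The authors deposited 1 table of estimated counts per Ensembl gene, with gene symbols and genomic intervals. Each deposited value is a multiple of 0.1. The 4 columns sum to nearly equal totals. The column of sleep restriction 2 holds whole numbers at 32544 genes, while the other columns hold decimal values, as a mean over 10 random draws of reads down to the depth of the shallowest library would. This reading comes from the values and from words in the table's own name, which also mark the counts as sense strand. It is not described in the labels. The 37 mitochondrial genes are all listed at 0, so the mitochondrial share of reads could not be used as a sign of RNA quality. The 16 rows without a usable gene symbol held between 0.0437% and 0.0563% of each total and stayed in the totals under their identifiers.

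The fraction of reads that each draw kept was estimated by maximum likelihood from how low values were spread over the multiples of 0.1. It was 0.59 for forced activity 2, between 0.01 and 0.07 for forced activity 1, and between 0.01 and 0.09 for sleep restriction 1. Sleep restriction 2 was taken as undrawn, with a total of 520275.6. By these estimates the counted reads before drawing, in units of 1e6, were about 0.882 for forced activity 2, at least 7.26 for forced activity 1 and at least 5.73 for sleep restriction 1. On simulated draws the estimate returned 0.29, 0.57 and 0.8 for true fractions of 0.3, 0.58 and 0.8. A true fraction of 0.05 gave 0.1 with a range of 0.01 to 0.14, so small fractions have only an upper limit. Replicate number therefore coincides with depth, the replicate 1 libraries being deep and the replicate 2 libraries shallow, and values within each such pair are given beside the pooled ones for the called gene, the called lists and the genes with the smallest p.

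Values were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr gene filter with its minimum count of 10, robust quasi-likelihood dispersions and Benjamini-Hochberg adjustment over all genes kept. A gene was called at an adjusted p under 0.05. The factors were 0.972 and 1.04 for forced activity 1 and 2, and 1.00 and 0.989 for sleep restriction 1 and 2. Normalised read counts are TMM-scaled counts per 1e6 counts (CPM), and errors on them are standard deviations over 2 libraries. Fold changes are log2 values of sleep restriction over forced activity, shrunken towards 0 by a prior count of 2. Their standard error (SE) was not fitted but calculated back, as the size of the shrunken change over the square root of its F statistic. Values within a pair of libraries are differences of log2 CPM with a prior count of 2. Averaging over draws lowers the counting noise of the deep libraries below that of a plain count, which the main test does not model. An alternative that scales each library to its effective count does.

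The design, 43 gene lists (29 of functions and 14 of cell types or other tissues), the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 34 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. With 2 residual degrees of freedom, camera with an estimated correlation could detect little, so its large adjusted p does not show that a list was unchanged. The preset correlation is itself an assumption that these libraries cannot check well. The genes named are those past the threshold with a proper symbol and a mean of at least 1 CPM, up to 12 per direction, filled up to 8 per direction by the smallest unadjusted p. To these come the 2 members with the smallest unadjusted p of each list described, or up to 4 where a member was called, and a fixed set of Arntl, Per2, Nr1d1, Dbp, Fasn, Pck1, Cyp7a1, Hspa5 and Fkbp5. Some genes that this rule names are not reported here. Any other gene is said to have been chosen after its values were seen, apart from Alb, which describes the libraries.

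On 20 simulated data sets with these means and library sizes, in which a median of 5051 genes was tested and 200 were changed, the test recovered 39% of 2-fold and 93.8% of 4-fold changes, and 4.2% of its calls were false. A list shifted by 0.4 on the log2 scale was called in 16 of the 20 sets, with 0.1 other lists called per set. Genes were drawn independently, with 1 common dispersion of 0.0196. These rates therefore do not cover genes that vary together or vary more than that, and they may be too favourable. They also hold for 200 changed genes, while the main test called 1 gene. With fewer genes changed the adjustment is stricter, so the shares recovered would be lower. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other dispersion settings and filters, removal of the 10 most abundant genes, a block for replicate number, removal of each library, and other thresholds. Unrounded values, effective counts and removal of the trend with genomic span were added after seeing the data. A floor of 3 counts corresponds to between 5.77 and 5.90 CPM. PCR reads without molecular identifiers are not independent molecules, so floors and counting intervals cover counting error only. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Coordinates are those of the deposited table, and exons and untranslated regions were not analysed here.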

Results

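Messenger RNA from rat liver was measured by sequencing in 2 libraries of forced activity and 2 of sleep restriction. Forced activity alone, in which animals were kept moving, served as the control for animals that were also restricted in sleep. The tabulated counts summed to 508202.6 and 520204.5 for forced activity 1 and 2, and to 515682.4 and 520275.6 for sleep restriction 1 and 2. These equal totals hide unequal depth, since both replicate 1 libraries were drawn down from deeper sequencing. The number of genes above 0 was 14008 and 14105 in the replicate 1 libraries, against 11943 and 10952 in the replicate 2 libraries. Albumin (Alb) took between 11.6% and 13.6% of the counts in each library, and 4986 of the 32545 listed genes were tested.

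The comparison asked which liver transcripts differ when restricted sleep is added to forced activity. RT1-A2, a classical class I gene of the rat major histocompatibility complex, fell to 24.4 ± 5.76 CPM under sleep restriction from 291 ± 125 CPM under forced activity (SD, 2 libraries each). It was the only gene past the threshold, with a log2 change of -3.37 (SE 0.36) and an adjusted p of 0.0149 in edgeR. Its counts were 179.1 and 104.3 under forced activity and 13.8 and 10 under sleep restriction, and it was lower in both pairs of libraries, by -3.56 on the log2 scale in the deep pair and -3.08 in the shallow pair. No gene was called higher. At an unadjusted p under 0.05 there were 212 genes, 145 higher and 67 lower, where 249.3 would be reached by chance, and DESeq2 also called 1 gene, RT1-A2.

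RT1-A2 (ENSRNOG00000030712.6) spans chromosome 20 from 5374985 to 5378539 in rn6, inside the listed interval of RT1-A1, which runs from 5351605 to 5421098 and had a log2 change of 0.14. RT1 genes have near-identical copies and differ between rat strains, so how reads were divided among them is uncertain. The 10 other class I genes tested, counting B2m, the light chain shared by class I molecules, had a median log2 change of -0.14 and ranged from -0.75 to 0.49. B2m itself had -0.03, and RT1-A1, B2m and this group of class I genes were chosen after their values were seen. Below the gene filter, and chosen after their values were seen, RT1-CE2 had 26.5 and 8.7 counts under forced activity and 5.9 and 2 under sleep restriction, and RT1-A3 had 3.5 and 3.5, then 14.1 and 8. The call of RT1-A2 did not hold with limma-voom (adjusted p = 0.152, log2 change -3.47), without robust estimation (0.0749, -3.37), without a gene filter (0.850, -3.40), or when any 1 library was left out, where its adjusted p lay between 0.584 and 0.99998 and its log2 change between -3.75 and -2.86.

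Other genes with the smallest p in the lower direction did not pass the adjustment in the main test, although some passed in alternative fits that take depth or replicate number into account. Cish and Socs2, feedback inhibitors of cytokine and growth hormone signalling, had log2 changes of -2.93 (SE 0.47) and -1.77 (SE 0.37), with adjusted p of 0.219 and 0.502. Cish measured 50.6 ± 30.3 CPM under forced activity and 3.05 ± 1.44 CPM under sleep restriction, where only 3 counts remained in all against 49, a ratio of 16.3 with an exact 95% counting interval of 5.27 to 81.9. This ratio is not shrunken, unlike the log2 change, and DESeq2 gave Cish -4.08 (SE 1.12, adjusted p 0.935). In the deep and shallow pairs Cish had -3.23 and -2.45, and Socs2 had -1.58 and -2.11. The immunoglobulin chains Igkc and Ighm had log2 changes of -1.36 (SE 0.23) and -1.15 (SE 0.25), and their segments share reads with related loci. Dusp1 and Dusp6, phosphatases that switch off MAP kinases, had -1.45 (SE 0.28) and -1.47 (SE 0.30), and Rgs3, a regulator of G-protein signalling, had -1.59 (SE 0.30). In the deep and shallow pairs the changes were -1.43 and -1.29 for Igkc, -1.36 and -0.99 for Ighm, -1.91 and -0.97 for Dusp1, -0.93 and -2.11 for Dusp6, and -1.50 and -1.73 for Rgs3.

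In the higher direction, none of the named genes passed the main test either, although Cyp4a2 passed in an alternative fit. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, measured 135 ± 75.5 CPM under forced activity and 376 ± 115 CPM under sleep restriction, a log2 change of 1.46 (SE 0.36) that was 0.63 in the deep pair and 2.43 in the shallow pair. Nedd4l, a ubiquitin ligase, had 1.12 (SE 0.25) with nearly equal values of 1.10 and 1.14 in the deep and shallow pairs. Cyp4a2, a fatty acid hydroxylase, had 1.19 (SE 0.28) at ENSRNOG00000030154.5 and 0.49 at a second entry of that symbol, and Cyp4a genes are close copies. Mia2 had 1.19 (SE 0.30), Arhgap5 had 1.10 (SE 0.28), Zfp354a had 1.0 (SE 0.26) and the acute phase protein Orm1 had 0.91 (SE 0.24). In the deep and shallow pairs the changes were 1.44 and 1.03 for Cyp4a2, 0.69 and 1.69 for Mia2, 0.81 and 1.35 for Arhgap5, 1.0 and 0.99 for Zfp354a, and 0.41 and 1.39 for Orm1.

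**Figure D1:**
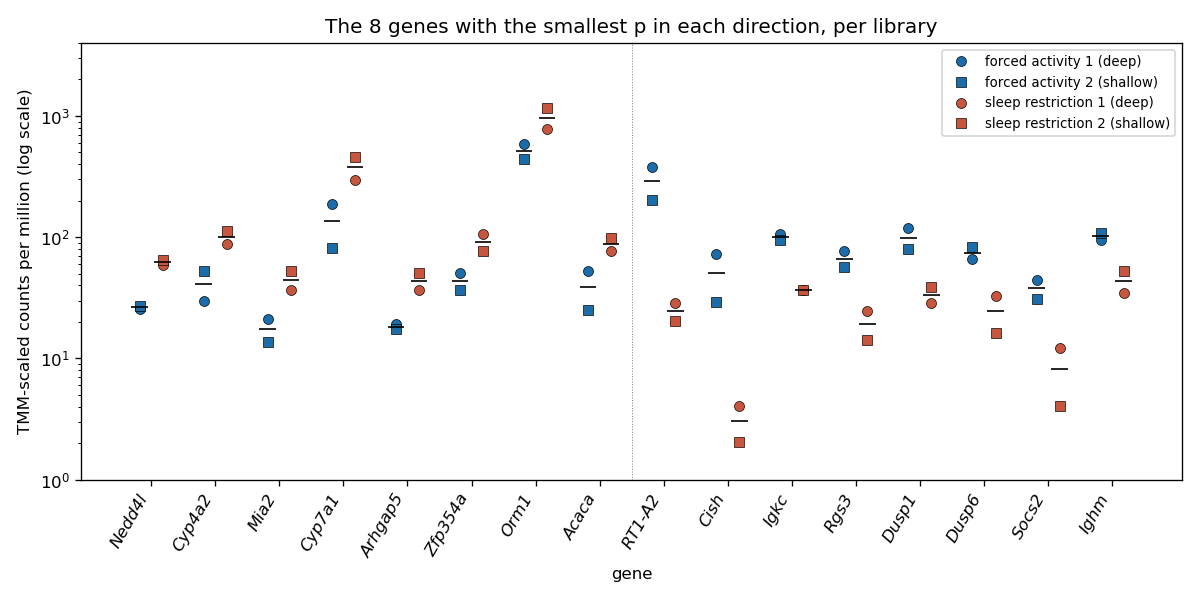
Normalised read counts (TMM-scaled CPM, log scale) of the 16 genes with proper symbols and the smallest p, 8 higher on the left and 8 lower on the right. Circles are replicate 1 and squares replicate 2 libraries, blue forced activity and red sleep restriction, with a bar at each group mean, and RT1-A2, the only called gene, drops from 379 and 203 CPM to 28.5 and 20.3 CPM.

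As a group, the genes of cytosolic ribosomal proteins were lower under sleep restriction. All 35 tested members had a negative log2 change, with a median of -0.29, and 31 were negative in both pairs of libraries. Another 8 listed members lay under the gene filter. Among them Rpl7a, Rpl8, Rpl35a, Rpl38, Rplp2 and Rps6 had 0 counts in every library, so how reads of this family were counted is uncertain. The medians were -0.22 in the deep pair and -0.36 in the shallow pair. Rpl37 went from 110 ± 2.07 to 75.3 ± 11.5 CPM (log2 change -0.52, SE 0.22) and Rps23 from 233 ± 3.84 to 163 ± 34.6 CPM (-0.50, SE 0.22), and neither passed the test alone. Camera gave the list an adjusted p of 6.74e-08, and an adjusted p = 0.943 with an estimated correlation. No member passed over all genes or adjusted over the list alone, and many ribosomal protein genes have processed copies that share reads. The Rpl37 entry runs only from 64336200 to 64336546 on chromosome 10, against a median span of 3.27 kb for the tested members. Whether it is such a copy was not tested. Across genes, the change also ran with the length of the genomic interval, with a Spearman rho of 0.267 (0.248 in the deep and 0.189 in the shallow pair). The rho was -0.057 for replicate 1 over replicate 2 and -0.045 for forced activity 2 and sleep restriction 1 over the remaining libraries. Genes with the shortest 10% of spans had a median change of -0.13 and those with the longest 10% had 0.13. This trend is therefore not confined to ribosomal protein genes, and genes are not independent replicates.

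Immediate early genes, which are induced within minutes of a stimulus, were lower as well. Of 7 tested members 6 were negative in both pairs, with a median of -1.0, and medians of -0.93 in the deep pair and -0.97 in the shallow pair. Dusp1 went from 99.3 ± 27.5 to 33.6 ± 7.19 CPM and Dusp6 from 74.7 ± 12.8 to 24.4 ± 11.5 CPM. Ier3 and Jun, chosen after their values were seen, had log2 changes of -1.0 (SE 0.26) and -1.17 (SE 0.34). Adjusted over the list alone, 4 members were lower, against 0 over all genes. Camera gave the list an adjusted p of 3.17e-06, and an adjusted p = 0.943 with an estimated correlation. The median was -0.43 without a gene filter, -0.53 with genes kept at 5 CPM in 2 libraries, -0.66 with effective counts and -0.59 without sleep restriction 2, each over more members, and the list was called in all 4. The 21 members under the filter summed to 113.6 and 78.5 counts under forced activity and to 67.2 and 55 under sleep restriction. Only 4 of them had fewer counts in both sleep restriction libraries than in either forced activity library, and 1 had more. Junb, Egr1 and Myc, chosen after their values were seen, held 22, 22.8 and 16 of the counts in forced activity 1.

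Genes of cholesterol synthesis and uptake were higher as a group. Of 22 tested members 19 had a positive log2 change, with a median of 0.40. Hmgcs1, a synthase early in the pathway, went from 298 ± 88.1 to 684 ± 305 CPM (1.19, SE 0.32), and Idi1, which isomerises isopentenyl diphosphate, from 74.1 ± 0.118 to 134 ± 40.3 CPM (0.82, SE 0.25). In the deep and shallow pairs Hmgcs1 had 0.37 and 1.91, and Idi1 had 0.49 and 1.10. The adjusted p in camera was 8.71e-05, and adjusted p = 0.943 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. The difference did not hold within both depths, since the list's median was -0.01 in the deep pair and 0.90 in the shallow pair, and without forced activity 2 its adjusted p was 0.467. Its median was 0.73 without forced activity 1, 0.16 without forced activity 2, 0.62 without sleep restriction 1 and 0.24 without sleep restriction 2.

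Fatty acid and triglyceride synthesis genes were higher in the same uneven way. Of 18 tested members 14 were positive, with a median of 0.24, which was 0.07 in the deep pair and 0.80 in the shallow pair. Acaca, which makes malonyl-CoA, went from 39.1 ± 19.6 to 87.5 ± 14.4 CPM (log2 change 1.10, SE 0.31), and Fasn, the fatty acid synthase, from 107 ± 35.1 to 217 ± 90.6 CPM (1.0, SE 0.32), and no member passed over all genes or adjusted over the list alone. In the deep and shallow pairs Acaca had 0.51 and 1.79, and Fasn had 0.21 and 1.73. Camera gave an adjusted p of 0.0225, and adjusted p = 0.943 with an estimated correlation. The call was lost without forced activity 2 (0.789), without sleep restriction 1 (0.151), without a gene filter (0.229), with genes kept at 5 CPM in 2 libraries (0.148) and with effective counts (0.231). Its median was 0.25 with effective counts, 0.16 without a gene filter and with genes kept at 5 CPM in 2 libraries, 0.61 without forced activity 1, 0.19 without forced activity 2 and 0.43 without sleep restriction 1.

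**Figure D2:**
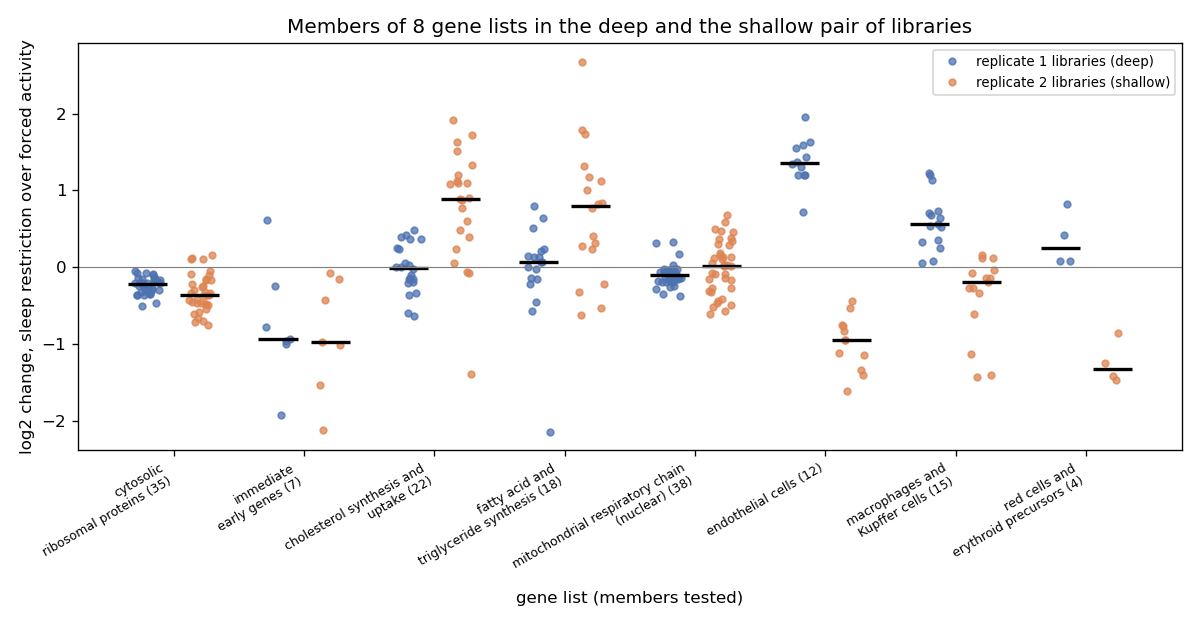
Log2 change of sleep restriction over forced activity for the tested members of 8 gene lists, within the deep pair (blue) and the shallow pair (orange), with a bar at each median. Ribosomal protein and immediate early medians lie below 0 in both pairs (-0.22 and -0.36, -0.93 and -0.97), while endothelial markers lie at 1.36 in the deep pair and -0.94 in the shallow pair.

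Markers of endothelial cells, which line the liver's vessels, moved in opposite directions within the pairs. The median of 12 tested members was 1.36 in the deep pair and -0.94 in the shallow pair, so that they were high in forced activity 2 and sleep restriction 1. Oit3 measured 8.48 and 23.4 CPM in forced activity 1 and 2 and 34.6 and 16.3 CPM in sleep restriction 1 and 2, and Flt4 measured 6.36 and 33.1, then 22.4 and 8.14 CPM. Macrophage markers had medians of 0.57 and -0.19 in the deep and shallow pairs, with Marco at log2 changes of 1.23 and -0.26 and Lyz2 at 1.13 and 0.12. The 4 tested red cell genes had 0.25 and -1.33, with Hba2 at 0.08 and -1.46 and Tfrc at 0.08 and -0.85. None of these lists was called between the groups in the main test, while the red cell list was called with the 5 CPM filter and with effective counts, and endothelial, macrophage or red cell lists were called when some single libraries were left out. The lipid synthesis lists ran the opposite way to the endothelial markers along this split, with median log2 differences of -0.41 for cholesterol synthesis and -0.31 for fatty acid synthesis in forced activity 2 and sleep restriction 1 over the other 2 libraries, against 1.11 for endothelial markers.

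The 4 libraries allow 3 splits into groups of 2, too few for a share of splits under 0.05. The labelled split called 1 gene and 4 lists. Setting replicate 1 against replicate 2 called 0 genes, with 470 at an unadjusted p under 0.05 in edgeR, and 5 lists. Setting forced activity 2 and sleep restriction 1 against the other 2 libraries called 1 gene and 8 lists, among them endothelial cells, macrophages, stellate cells, red cells and both lipid synthesis lists. At the preset correlation the ribosomal protein and immediate early lists were called in the labelled split and in neither of the others, the difference between splits was not tested, and in the labelled split 0 lists were called with an estimated correlation (smallest adjusted p 0.943). That 1 gene was Scd1, the stearoyl-CoA desaturase, chosen after its values were seen, with 209.3 and 26.9 counts in forced activity 1 and 2 and 47.7 and 176 in sleep restriction 1 and 2.

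Clock, stress and glucose genes did not differ past the threshold. Among clock genes, Per3 had a log2 change of -0.74 (SE 0.25), close to equal in the deep (-0.71) and shallow (-0.77) pairs, and Usp2 had 0.68 (SE 0.27). Per2 had -0.32 (SE 0.31), Dbp 0.08 (SE 0.50) and Nr1d1 0.17 (SE 0.45), with Per2, Dbp and Nr1d1 each of opposite sign in the 2 pairs, and Arntl was too low to test at 0.8, 1, 2.8 and 1 counts. Of 21 endoplasmic reticulum stress genes 16 were negative, with Hspa5, the main chaperone, at -0.09 (SE 0.24), Sdf2l1 at -0.71 (-0.36 to -1.19 with 1 library left out) and Dnajb9 at 0.45 (0.10 to 0.72), and the list's adjusted p was 0.244. Pck1, the first committed enzyme of gluconeogenesis, had -0.06 (SE 0.40) and was 0.39 in the deep pair and -0.84 in the shallow pair, while Gpt2 had 0.44 (0.21 and 0.74 in those pairs) and Fbp1 0.28 (0.22 and 0.34). With 1 library left out Gpt2 ran from 0.13 to 0.82 and Fbp1 from 0.17 to 0.39. The gluconeogenesis list had an adjusted p of 0.830, with a median of -0.04 against a mean of 0.14, and periportal, secreted protein and oxidative stress lists, none of them called, also had a median that differed in sign from the mean or the test.

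Glucocorticoid targets had a median of 0.03, a mean of -0.26 and a downward test with an adjusted p of 0.244, so the sign of the median differed from that of the mean and the test. Dusp1 and Serpina6, the corticosteroid-binding globulin, were lower when adjusted over the list alone, against 0 over all genes. Serpina6 went from 555 ± 47.3 to 291 ± 109 CPM (log2 change -0.92, SE 0.25), with -0.50 in the deep pair and -1.44 in the shallow pair. Fkbp5, a widely used glucocorticoid-induced gene, had -0.09 (SE 0.29). In the growth hormone list 2 members, Cish and Socs2, were lower when adjusted over the list alone, against 0 over all genes, and the list's adjusted p was 0.427.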

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

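Effective counts and the other 2 alternatives added after seeing the data are named here with those planned. RT1-A2 was called under other scalings, DESeq2, the older quasi-likelihood, the 5 CPM filter (planned as stricter, though it kept 8851 genes), removal of the 10 most abundant genes, unrounded values, effective counts and the replicate block. The count of called genes was 0, with 0 lower, under limma-voom, without robust estimation and without a filter, and 0 to 0 with each library left out, where a lone library is assumed to vary like the other group. It was 4 (2 higher, 2 lower, RT1-A2 and Cish, at 0.00718) with effective counts. The labels do not say that replicate numbers pair animals, and with 2 pairs (correlation of deviations 0.207) the numbers were not taken as paired; a replicate block gave 11 genes, 2 higher and 9 lower, among them 7 named genes the main test did not call: Cish (adjusted p 0.000176), Igkc and Rgs3 (0.0171), Socs2 (0.0276), and Dusp1, Ighm and Cyp4a2 (0.0417). Called lists numbered 0 with an estimated correlation and 0 by fry, and 4 to 12 with each library left out, 8 without forced activity 2 and 12 without sleep restriction 2. Adjusted p with an estimated correlation and by fry was 0.943 and 0.917 for both lipid lists, 0.943 and 0.917 for immediate early genes, and 0.943 and 0.896 for ribosomal proteins. With each library left out it ran from 2.59e-07 to 0.467 for cholesterol synthesis and from 0.00237 to 0.789 for fatty acid synthesis, which had 0.229 without a filter, 0.148 with the 5 CPM filter and 0.231 with effective counts. Log2 changes of uncalled genes that changed sign with a library left out ranged from -0.0129 to 0.78 for Stat2, -1.01 to 0.26 for Tfrc, -0.99 to 0.88 for Flt4, -0.58 to 1.23 for Dbp, -0.94 to 0.47 for Pck1, -0.73 to 0.27 for Per2, -0.40 to 0.16 for Hspa5, -0.37 to 0.13 for Fkbp5 and -0.44 to 1.16 for Nr1d1; with effective counts Flt4 had 0.27, Dbp -0.13 and Nr1d1 -0.21. Leaving out a library leaves fewer samples; otherwise the cause was not tested. In simulations at this depth with 200 genes changed, 39% of 2-fold changes were recovered, so smaller changes of single genes were mostly not detectable. With fewer genes changed the adjustment is stricter and that share would be lower.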

Other observations

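Genes of drug metabolism and sugar storage had positive changes that did not pass the test. Cyp3a18 went from 597 ± 125 to 968 ± 329 CPM and Cyp3a23/3a1, a steroid and drug hydroxylase, from 186 ± 31.2 to 270 ± 15.8 CPM, in a list of 26 tested members of which 16 were positive (adjusted p 0.346 in camera). Gbe1, the glycogen branching enzyme, had a log2 change of 0.75 (SE 0.28), 0.09 in the deep and 1.39 in the shallow pair, and 13 of 20 tested members of its list were positive (adjusted p 0.427). Bile acid genes were mixed, with 11 of 19 positive (adjusted p 0.427) and Abcg5, a subunit of a sterol transporter, at -0.81 (SE 0.34), -0.05 in the deep and -1.53 in the shallow pair.

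Lipoprotein genes were mostly negative, 13 of 20 and all 13 in both pairs, with an adjusted p of 0.346 in camera. Apoa1, the main protein of high-density lipoprotein, went from 2017 ± 215 to 1365 ± 212 CPM (log2 change -0.56, SE 0.20), while Abca1 had 0.44 (SE 0.23). In the deep and shallow pairs Apoa1 had -0.30 and -0.83, and Abca1 had 0.08 and 0.80. In fatty acid oxidation 17 of 27 members were positive (adjusted p 0.742), but the members with the smallest p were negative. They were Acaa2 at -0.40 (SE 0.18) and Pdk4 at -0.86 (SE 0.41), and Pdk4 ran from -0.33 to -1.74 with 1 library left out. This holds with Cyp4a2 taken by its more abundant entry, at 0.49 (unadjusted p 0.122 in edgeR). Its other entry, at 1.19, had a smaller unadjusted p of 0.00157 and was not in the list. Ifi27 had -0.52 (SE 0.23) and Stat2 0.44 (SE 0.27) in an interferon list with 5 of 8 positive (adjusted p 0.830), and Cp had 0.42 (SE 0.21) in an acute phase list with 11 of 21 positive (adjusted p 0.427).

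All tests weighed in the following were chosen after the results were seen. RT1-A2 was lower in both libraries of sleep restriction. Depth is argued against, since the 2 deep libraries alone differed by -3.56 on the log2 scale. A shift of its reads to other class I copies in the table is argued against, since the 30 other class I genes together changed by -60.4 counts while RT1-A2 lost 129.8, although reads that map to several copies may not have been counted at all. Different class I alleles in the animals may explain it and stay open: 2 of 13 other RT1 genes reached an unadjusted p under 0.05 (binomial p 0.135), and no genotype was used here. That binomial p takes the 13 genes as independent, although RT1 genes are inherited together. It also leaves out RT1-CE2 and RT1-A3, which lay under the gene filter, so it cannot decide. Sleep restriction itself stays open, untested apart from that.

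Ribosomal protein genes were lower together. Depth is argued against, since the median was -0.22 in the deep pair with an upper quartile of -0.16. The trend with genomic span may account for part of it: removing that trend moved the median from -0.30 to -0.19 and left the list's adjusted p at 0.00399, which argues against the trend as the whole cause. Poor yield of short transcripts may also contribute and stays open: nuclear respiratory chain genes had a median of -0.0230, but they span 7.11 kb at the median against 3.27 kb for the ribosomal genes, the 449 genes with the shortest 10% of spans and no Rpl or Rps symbol had a median of -0.12, and transcript lengths were not used here. An effect of sleep restriction on these genes is a hypothesis found in these libraries, and it rests on the preset correlation.

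Endothelial markers were high in forced activity 2 and sleep restriction 1. Depth is argued against, since all 12 tested members differed between replicates 1 and 2 with opposite signs in the 2 groups. A lower share of hepatocytes alone would raise other cell types alike. Yet the endothelial median of 1.11 (quartiles 1.0 and 1.35) exceeded that of macrophages (quartiles 0.31 and 0.65) by 0.677. Macrophage, stellate and red cell markers were also raised there, with medians of 0.44, 0.39 and 0.85, so a lower share may still contribute. More endothelial cells in the piece of liver taken, alone or together with that, may explain the pattern and was not tested. Swapped labels of 2 libraries with the same replicate number cannot be told apart from the labelled design. The split that such a swap would make gave 1 called gene, Scd1. The bound set for excluding a swap, no more genes than the labelled split, was met only by that tie, which leaves no margin. Lists were not part of that bound. In camera at the preset correlation this split called 8 lists (smallest adjusted p 8.89e-29), against 4 in the labelled split (6.74e-08). No group in the labels follows this pattern, so no biological explanation was tested.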
